A study of Mus musculus with 48 samples.

How the data were processed

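Poly(A) RNA was sequenced from the medial prefrontal cortex of C57BL/6 mice, an inbred laboratory strain. Per the labels' protocols, mice had a voluntary choice of 15% ethanol every other day for 60 days and were killed after the last bottle was taken away, and control mice drank water. A separate cohort received an injection of 1.5 mg/kg bacterial lipopolysaccharide (LPS), a Toll-like receptor 4 ligand, or saline and was killed 1 week later. The minced tissue of each drinking mouse gave a small portion that was kept as total homogenate, and the rest was dissociated, cleared of myelin on Percoll and enriched with magnetic beads against CD11b, the integrin encoded by Itgam. The cells bound by the beads are called microglia here, although CD11b is also carried by border macrophages, monocytes and neutrophils.

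The values in the deposited files are whole-number read counts per gene symbol, 1 file per library, and each file held 24062 genes and 5 tally rows. Per the submitters' processing notes, bcl2fastq 2.15.0.4, FastQC, STAR, HTSeq and DESeq2 were used with the mouse build mm10, with no settings or order recorded. The strand setting, the annotation and the treatment of read mates in the counting are not given in the sources used here. Genes that overlap, lie antisense to each other or have near-identical copies are therefore uncertain, and Hspa1a and its copy Hspa1b are examples. The tally rows (reads outside genes, ambiguous, unaligned or multiply aligned) stayed out of library sizes and tests. Reads outside annotated genes made up 27.1% ± 4.20 (SD, n = 10) of uniquely aligned reads in ethanol homogenates and 22.5% ± 1.91 (SD, n = 9) in water homogenates. In microglia they made up 26.0% ± 5.49 (SD, n = 10) with ethanol, 27.4% ± 11.8 (SD, n = 8) with water, 32.3% ± 8.44 (SD, n = 5) with LPS and 31.3% ± 6.06 (SD, n = 5) with saline.

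Samples were grouped by treatment and preparation as the labels give them, with 48 samples listed and 47 libraries with counts. The microglial library of water mouse 26, which its label marks as taken out, was not analysed here. The libraries with counts numbered 10 ethanol and 9 water homogenates, 10 ethanol and 8 water microglia, and 5 LPS and 5 saline microglia, each from its own mouse within a group. No 2 libraries of a group agreed within sampling noise: over genes with at least 20 counts the lowest chi-square per degree of freedom between libraries of a group was 13.2. Y-linked genes were expressed in all libraries, and Xist reached at most 1.50 CPM, the count scaled to the library total in genes.

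Differential expression was tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood F-test, with TMM scaling, the filterByExpr filter on low counts and Benjamini-Hochberg adjustment at 0.05 over the genes tested. All adjusted p-values for genes come from this test unless another tool is named. CPM values were computed from the deposited counts, and log2 fold changes are those of the edgeR fit. The SE given with them is the size of the log2 fold change divided by the square root of its F statistic. For genes with hardly any counts in a group it is only a rough guide. Each comparison was fitted on its own groups: ethanol against water in microglia, ethanol against water in homogenate, LPS against saline in microglia, microglia against homogenate in water mice, and the interaction that sets the ethanol response of microglia against that of homogenate. Gene lists were tested with camera from limma 3.58.1, with a preset correlation between genes of 0.01 and adjustment over the lists of a comparison, and again with the correlation estimated from the data. The 38 lists, written before the data were examined, cover markers of brain, blood and border cell types, immune pathways, stress responses, metabolism and synaptic genes. Of their 839 symbols 836 were found in the files, lists with fewer than 5 measured members were not tested, and the sex-linked list served only as the check above. The design, the alternative settings and the rule for named genes were also set before the data were examined.

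Named genes were chosen by a fixed rule. In each comparison these are, among genes past the threshold with at least 1 CPM in a group, the 8 largest rises and the 8 largest falls and the 4 smallest p-values in each direction, with predicted genes left out, or all of them where fewer than 16 passed. Up to 4 members with the smallest p were added from each list that passed and from the interferon, Toll-like receptor, TGF-beta, cytokine, major histocompatibility, homeostatic and disease-associated lists, together with a fixed set of microglial and cell type markers. Gene positions are from the GENCODE M21 annotation of GRCm38, the assembly that mm10 names.

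Homogenate and microglia with the same mouse number came from the same mouse, by the protocol. After group means were taken off, the deviations of the 18 pairs correlated across genes with a median of 0.0205 (range -0.0178 to 0.116). With microglia of other mice of the same treatment the median was -0.0021. Among the 10 ethanol or 8 water microglia of their treatment, 6 of the 18 homogenates correlated best with their own partner. The alternative settings were DESeq2 1.42.0, voom with sample quality weights, RLE scaling, no filter or a stricter filter on low counts, the mouse as a block, a score of other cell types as a covariate, leaving out each library in turn, and the sequencing run. The score was the mean log2 CPM of neuronal, astrocyte, oligodendrocyte and endothelial markers. The run is not given by the labels. It was inferred from the sample-sheet index in the file names, which repeats 3 times and so points to 3 runs, with all LPS and saline libraries in the third. Fits were tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. Apart from planted changes, each gene had the same mean in all groups, and genes varied independently of each other. No library was made to stand apart, so the shares recovered can overstate those in the real data. At 2-fold the fits recovered 66% of changed genes in the microglial ethanol comparison, 82% in the homogenate, 45% in the interaction, 44% in the LPS comparison and 66% between preparations, and at 4-fold 75%, 91%, 70%, 66% and 79%.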

Results

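RNA was sequenced from homogenates of 10 ethanol and 9 water mice and from isolated microglia of 10 ethanol, 8 water, 5 LPS and 5 saline mice. Total counts in genes (M, mega) averaged 38.02 M ± 13.2 (SD, n = 10) in ethanol homogenates and 51.02 M ± 13.1 (SD, n = 9) in water homogenates. In microglia they averaged 27.2 M ± 4.54 (SD, n = 10) with ethanol and 27.3 M ± 9.70 (SD, n = 8) with water. After LPS they averaged 29.6 M ± 5.33 (SD, n = 5) and after saline 27.2 M ± 7.83 (SD, n = 5). Libraries ranged from 9.72 M, in the microglia of water mouse 24, to 67.5 M in the homogenate of water mouse 17. No molecular identifiers are named in the labels, so intervals and floors given here cover counting error only. Among detected genes, 58.9% ± 3.75 (SD, n = 8) had an even count in water microglia and 51.5% ± 1.12 (SD, n = 9) in water homogenates. Part of the microglial counts may therefore come in pairs, whose cause was not tested. Floors and intervals treat counts as independent and can look firmer than they are.

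The comparison of microglia with homogenate in water mice set isolated cells against whole tissue. Homogenate was not dissociated, so gains and losses by the CD11b enrichment and changes during the isolation cannot be told apart. Genes of resting microglia were far higher in the isolated cells, with Csf1r, the receptor for colony-stimulating factor, at 9960 ± 1127 CPM (SD, n = 8) against 157 ± 20.1 CPM (SD, n = 9), a log2 fold change of 6.06 (SE 0.10). The fractalkine receptor Cx3cr1 rose by 6.04 (SE 0.08), the microglial surface protein Tmem119 by 6.01 (SE 0.10), the purinergic receptor P2ry12 by 5.89 (SE 0.11) and Itgam by 5.88 (SE 0.08) on the log2 scale. Neuronal and glial genes were lower in the isolated cells. The synaptic vesicle fusion protein Snap25 changed by -7.40 (SE 0.36), the astrocyte filament Gfap by -6.58 (SE 0.46) and the water channel Aqp4 by -5.18 (SE 0.37). Myelin basic protein Mbp changed by -4.45 (SE 0.42) and the endothelial tight junction gene Cldn5 by -1.91 (SE 0.28). All of these passed in edgeR's test, with the largest adjusted p at 4.94e-06 for Cldn5. In all, 12712 of 15057 genes differed, 5314 higher and 7398 lower in microglia, and the median log2 fold change of all genes was -0.37.

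All 25 measured homeostatic microglial genes rose, and the list passed camera (adjusted p = 9.05e-45, and adjusted p = 0.0124 with an estimated correlation). The Toll-like receptor pathway rose in 33 of 36 genes and fell in 1, with Tlr9 at 6.40 (SE 0.12) and the adaptor Myd88 at 4.40 (SE 0.11). It passed as a list (adjusted p = 6.18e-16, and adjusted p = 0.00230 with an estimated correlation). NF-kB cytokine genes rose in 26 of 28 and fell in 1, among them Nlrp3 at 9.06 (SE 0.25) and Tnf at 10.97 (SE 0.44). Lysosomal and phagocytic genes rose in 26 of 32 with 4 falling, and unfolded protein response genes in 20 of 24 with 3 falling. These lists held with an estimated correlation at adjusted p = 0.0287, adjusted p = 0.0418 and adjusted p = 0.0418. With the stricter filter or the mouse as a block, both with an estimated correlation and added after seeing the data, the homeostatic (adjusted p = 0.0575 and 0.0504), NF-kB (adjusted p = 0.0575 and 0.0504) and lysosomal lists (adjusted p = 0.115 and 0.134) did not pass. The Toll-like receptor list did not with the block (adjusted p = 0.134), nor the unfolded protein response list with the stricter filter (adjusted p = 0.0575) or RLE scaling (adjusted p = 0.0669). Immediate early genes, which tissue dissociation also induces, rose in 20 of 24 and fell in 3, with Jun at 7.10 (SE 0.11) (adjusted p = 6.43e-14, and adjusted p = 0.0517 with an estimated correlation). Adjusted over the list alone, the numbers that rose or fell in these 6 lists were those given here.

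All 25 measured neuronal markers, 20 astrocyte markers, 15 oligodendrocyte precursor markers, 28 glutamate receptor and synapse genes and 19 GABA receptor genes were lower in microglia. So were 47 of 47 oxidative phosphorylation genes, 22 of 23 cholesterol synthesis genes and 15 of 18 glycolysis genes. The same numbers were called when adjusted over the list alone. Their lists passed with the preset correlation only, with adjusted p between 0.2009 and 0.3401 with an estimated correlation. Of 20 oligodendrocyte markers 19 were lower, and the list did not pass (adjusted p = 0.141, and with the mouse as a block adjusted p = 0.00316, or adjusted p = 0.456 with an estimated correlation). Calb2, the calcium-binding protein calretinin, had no counts in any microglial library and was at least 913-fold lower, counted against a floor of 3 counts over the group. Pld5, Agt and Clec18a, also without counts, were at least 551-fold, 545-fold and 484-fold lower. Slc17a6, a vesicular glutamate transporter with 1 count in microglia, was 3601-fold lower with a counting interval (95%) that starts at 646.

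Markers of border macrophages and neutrophils, which also bear CD11b, were higher in the isolated cells too. All 15 border macrophage markers rose, with Stab1 at 5.22 (SE 0.27) and the mannose receptor Mrc1 at 4.56 (SE 0.49), and the list passed at adjusted p = 0.00778 (adjusted p = 0.537 with an estimated correlation). All 11 measured neutrophil markers rose (adjusted p = 0.0139, and adjusted p = 0.570 with an estimated correlation), and the list missed the threshold with the stricter filter on low counts (adjusted p = 0.0682). Their level rested on water mouse 19. The granule protein Ngp was at 561 ± 1489 CPM (SD, n = 8). Without this microglial library its log2 fold change was 6.33 in place of 10.19, that of Chil3 6.77 in place of 10.65. That of Irg1 was 7.24 in place of 10.95 and that of S100a9 6.24 in place of 9.57. Of 10 measured monocyte markers 8 rose and 1 fell, and the list did not pass (adjusted p = 0.462, and with the mouse as a block adjusted p = 0.0317, or adjusted p = 0.412 with an estimated correlation).

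**Figure D1:**
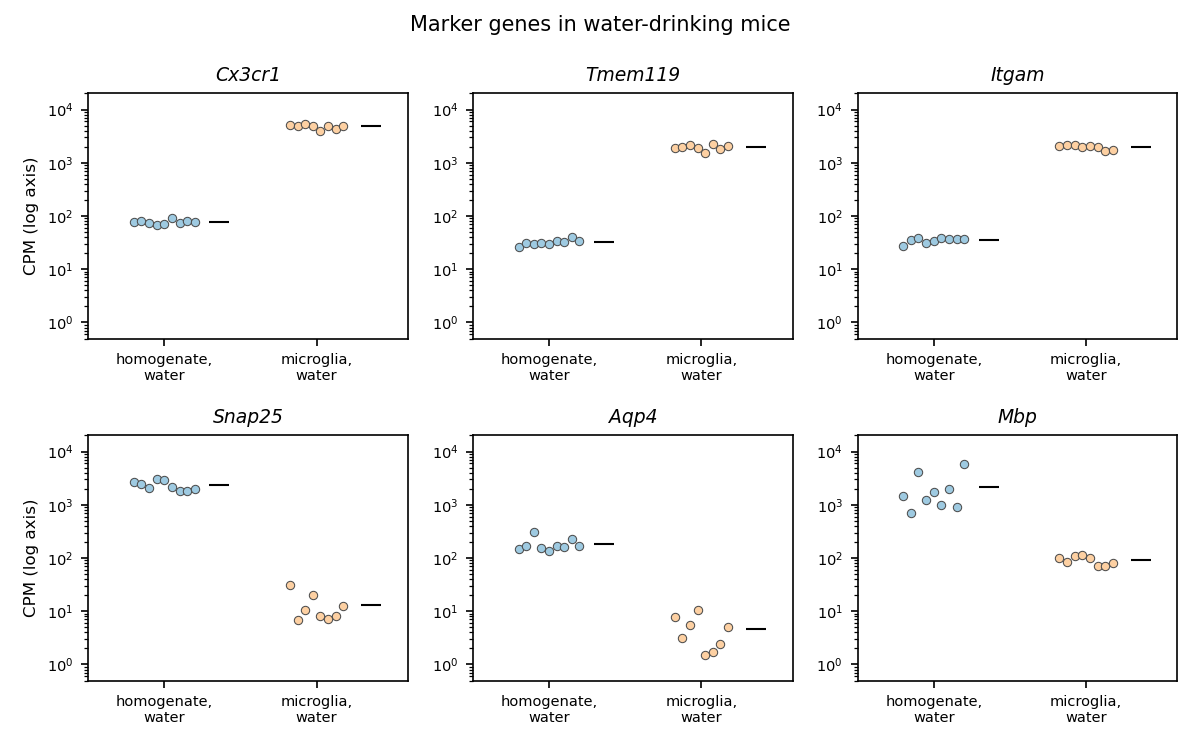
CPM on a log axis of 6 marker genes in each library of water mice, as points for 9 homogenates and 8 microglial preparations, with a bar at the mean. Cx3cr1, Tmem119 and Itgam were higher in all 8 microglial libraries, and Snap25, Aqp4 and Mbp were lower in all 8.

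Ethanol drinking was compared with water in isolated microglia. Adamts16, a secreted metalloprotease that acts on the extracellular matrix, was the gene that passed in edgeR's test. It rose to 37.1 ± 8.40 CPM (SD, n = 10) from 18.2 ± 3.63 CPM (SD, n = 8), a log2 fold change of 0.99 (SE 0.15, adjusted p = 0.0161). Its lowest ethanol library, at 26.6 CPM, lay above its highest water library, at 23.3 CPM. In saline microglia, controls of the separate LPS cohort, Adamts16 stood at 36.0 ± 3.54 CPM (SD, n = 5), so the ethanol level was also that of a control group. Of 13223 genes tested 1011 had an unadjusted p under 0.05, 7.65% of them. Adamts16 lies on chromosome 13 at 70727802 to 70841811 on the minus strand and codes for protein. The other tools gave 50 genes (DESeq2) and 10 genes (voom).

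Immediate early genes, transcription factors and other genes switched on within minutes of stimulation, rose as a list in ethanol microglia (camera adjusted p = 4.13e-17, and adjusted p = 0.0487 with an estimated correlation). Of 23 measured members 22 had a positive log2 fold change, with a median of 0.22. None passed over all genes tested by edgeR, while 13 were called when adjusted over the list alone. Btg2, an antiproliferative immediate early gene, was at 0.29 (SE 0.06, adjusted p = 0.0888) and the zinc finger factor Egr1 at 0.38 (SE 0.08, adjusted p = 0.141). Ier2 was at 0.33 (SE 0.07, adjusted p = 0.147) and the AP-1 subunit Fosb at 0.39 (SE 0.09, adjusted p = 0.168). The median log2 fold change of the list was 0.25 within the first inferred run and 0.18 within the second. Without water mice 19 and 24, whose libraries stood apart, a choice made after seeing the data, the list was at adjusted p = 3.86e-13, and its call with an estimated correlation was lost (adjusted p = 0.0943). That call was also lost with the stricter filter (adjusted p = 0.0585) and with the score of other cell types as a covariate (adjusted p = 0.0762), 2 fits added after seeing the data.

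A set of immune and microglial genes fixed before the data were seen did not pass. The LPS receptor Tlr4 had a log2 fold change of -0.25 (SE 0.12, adjusted p = 0.634), and its co-receptor Cd14 -0.14 (SE 0.09). The cytokine Tnf was at -0.18 (SE 0.09), Il1b at 0.0013 (SE 0.21), the lipid carrier Apoe at -0.08 (SE 0.11), the growth factor Tgfb1 at 0.02 (SE 0.04) and its receptor Tgfbr1 at -0.03 (SE 0.07). P2ry12, Cx3cr1 and Tmem119 were at 0.04, 0.08 and 0.08, with SE of 0.07, 0.06 and 0.07. The Toll-like receptor list (adjusted p = 0.818), the TGF-beta list (adjusted p = 0.560), the NF-kB cytokine list (adjusted p = 0.934) and the interferon list (adjusted p = 0.756) did not pass. The lists of major histocompatibility class I (adjusted p = 0.788) and class II (adjusted p = 0.739) and the disease-associated list (adjusted p = 1.000) did not pass. The median and the mean log2 fold change had opposite signs for TGF-beta (0.02 and -0.06), class I (-0.01 and 0.01) and class II (0.02 and -0.01), and the disease-associated list had both below 0 (-0.04 and -0.20) with a test direction above 0. In these lists 1 TGF-beta gene was called when adjusted over the list alone, Ski at 0.27 (SE 0.06, adjusted p = 0.169 over all genes), a repressor of SMAD transcription factors, and no member of the other 6 lists was.

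Homeostatic microglial genes rose as a list (adjusted p = 0.0110, and adjusted p = 0.970 with an estimated correlation), with 20 of 25 positive and a median of 0.08. Without water mice 19 and 24 this call was lost (adjusted p = 0.715, median 0.02). The nucleotide receptors P2ry6 at 0.23 (SE 0.09) and P2ry13 at 0.19 (SE 0.08) did not pass. Oligodendrocyte markers were mostly lower in microglia than in homogenate of water mice. With ethanol they rose as a list in microglia (adjusted p = 1.91e-05, and adjusted p = 0.970 with an estimated correlation), with 20 of 20 positive and Mog at 1.11 (SE 0.44, adjusted p = 0.541). Border macrophage markers fell as a list (adjusted p = 0.0219), with 3 of 15 positive and F13a1 at -0.70 (SE 0.23, adjusted p = 0.398). Glycolysis genes fell as a list (adjusted p = 0.0251), with 1 of 18 positive and Gapdh at -0.22 (SE 0.09, adjusted p = 0.574). Their median was -0.14, and without water mice 19 and 24 it was -0.04 and the call was lost (adjusted p = 0.428). With an estimated correlation the border macrophage and glycolysis lists were at adjusted p = 0.970. No member of these 4 lists was called, over all genes or adjusted over the list alone. Neutrophil markers had a median of -2.35 with 9 of 12 called lower when adjusted over the list alone and none over all genes, and the list did not pass (adjusted p = 0.890). Without water mice 19 and 24 their median was 1.05 and the list rose (adjusted p = 2.34e-14, and adjusted p = 0.154 with an estimated correlation). Other lists passed in that fit and not in the full comparison. Monocyte markers rose, with a median of 0.60 in place of -1.32 (adjusted p = 0.0189, against 0.172), and so did ribosomal protein genes, with a median of 0.06 in place of -0.0097 (adjusted p = 0.00299, against 0.796). Heat shock genes fell, with a median of -0.29 in place of -0.13 (adjusted p = 0.00299, against 0.725), as did unfolded protein response genes at -0.12 in place of -0.08 (adjusted p = 0.00299, against 0.127). Endothelial markers fell at -0.18 in place of -0.10 (adjusted p = 0.0107, against 0.220). With an estimated correlation these 5 lists were at adjusted p = 0.774, 0.919, 0.774, 0.376 and 0.889. Endothelial markers also passed as lower in all libraries with the score of other cell types, which includes them, as a covariate (median -0.22, adjusted p = 0.00233, and adjusted p = 0.854 with an estimated correlation).

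The call of Adamts16 was lost without water mouse 16 (adjusted p = 0.0666), 18 (adjusted p = 0.0571) or 21 (adjusted p = 0.0610). Within the first inferred run its log2 fold change was 1.14 (adjusted p = 0.993) and within the second 0.78 (adjusted p = 0.324). Its 10 alternatives other than left-out libraries spanned adjusted p from 3.28e-06 to 0.993.

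In total homogenate 123 of 15215 genes differed between ethanol and water mice, 93 higher and 30 lower with ethanol, and 6 of them by at least 2-fold. Ethanol homogenates also held a larger share of reads outside genes. With that share as a covariate 0 of these genes were called, so the parts of ethanol and of this share cannot be told apart. Cyr61, a secreted matrix protein induced by growth factors, rose to 29.0 ± 16.8 CPM (SD, n = 10) from 8.23 ± 3.53 CPM (SD, n = 9), a log2 fold change of 1.83 (SE 0.30, adjusted p = 0.00870). Npas4, a transcription factor switched on by neuronal activity, rose by 1.68 (SE 0.27, adjusted p = 0.00870). Btg2 rose by 1.51 (SE 0.29, adjusted p = 0.0200), the endothelial early response gene Apold1 by 1.12 (SE 0.23, adjusted p = 0.0269) and the AP-1 subunit Junb by 1.01 (SE 0.22, adjusted p = 0.0374). The largest fall was that of Aldh1a1, a retinaldehyde dehydrogenase that also oxidises acetaldehyde, to 18.7 ± 6.02 CPM (SD, n = 10) from 39.2 ± 16.1 CPM (SD, n = 9), a log2 fold change of -1.05 (SE 0.23, adjusted p = 0.0345). The count of genes moved by over 1.5 times in 13 of the 19 fits without 1 library, from 39 without water mouse 18 to 275 without ethanol mouse 1. DESeq2 called 526 genes, voom 568 and edgeR without a filter on low counts 62.

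Other rises included the integrin subunit Itga8 at 1.00 (SE 0.15), Lrrc29 at 0.96 (SE 0.21), the axonemal dynein Dnah5 at 0.95 (SE 0.16) and Rccd1 at 0.52 (SE 0.08). They also included the telomere helicase Rtel1 at 0.49 (SE 0.07) and Rbm33 at 0.35 (SE 0.06). Other falls included Nostrin, a trafficking factor of endothelial nitric oxide synthase, at -0.98 (SE 0.22), Fam53b at -0.61 (SE 0.09), complexin Cplx1, which controls vesicle fusion, at -0.58 (SE 0.13) and Zbtb7b at -0.52 (SE 0.12). They also included Luzp1 at -0.50 (SE 0.11), the kinase Nuak1 at -0.42 (SE 0.08), Dusp3 at -0.33 (SE 0.06) and Pepd at -0.28 (SE 0.05). Their adjusted p lay between 0.00601 and 0.0446. Of the 24 named genes past the threshold in homogenate 12 lost their call without at least 1 library: Apold1, Junb, Lrrc29, Aldh1a1, Nostrin, Cplx1, Zbtb7b, Luzp1, Herpud1, Pfkfb3, Fkbp4 and Ndufs7. Cyr61 was not matched by symbol in the annotation used, Npas4 lies on chromosome 19 at 4984355 to 4990316 and Aldh1a1 on chromosome 19 at 20492715 to 20643465.

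**Figure D2:**
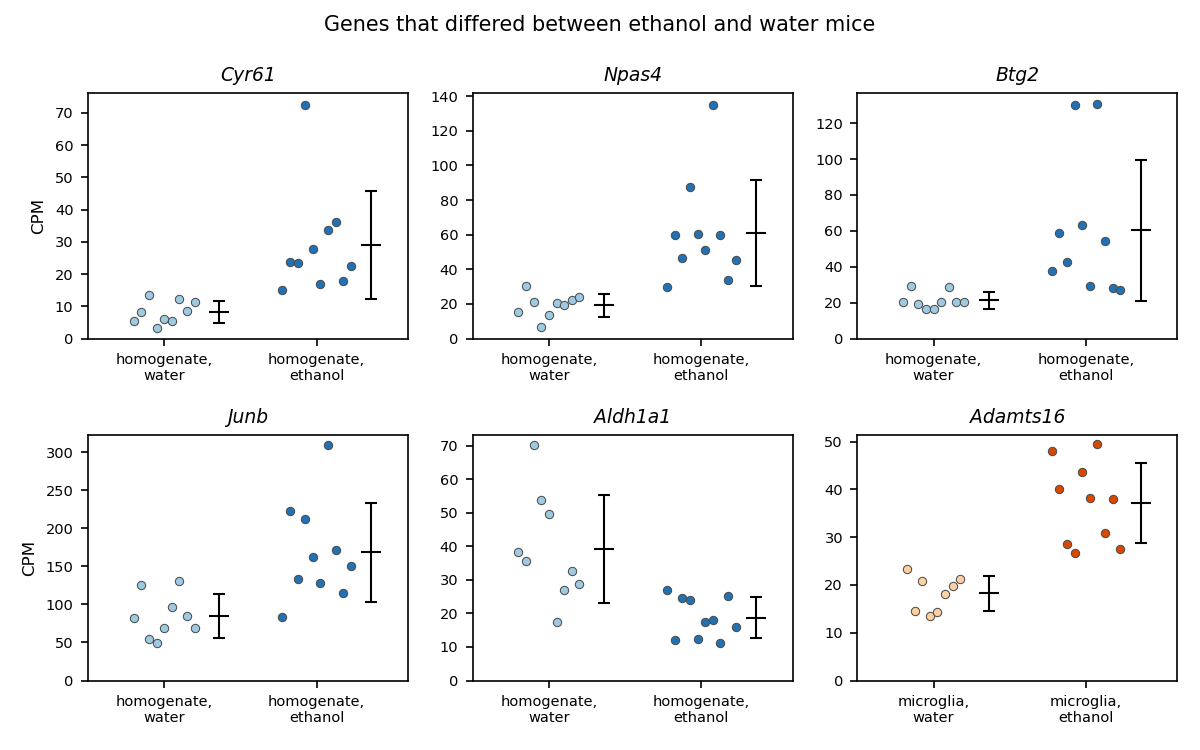
CPM per library of 5 genes in homogenate (9 water and 10 ethanol mice) and of Adamts16 in microglia (8 water and 10 ethanol mice), as points, with the mean and SD as a bar and whiskers. Cyr61, Npas4, Btg2 and Junb were higher and Aldh1a1 lower in ethanol homogenates, and the Adamts16 values of water and ethanol microglia did not overlap.

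The immediate early list rose in homogenate (camera adjusted p = 8.61e-10, and adjusted p = 0.326 with an estimated correlation), with 21 of 24 members positive and a median of 0.37. Over all genes tested 4 members rose and none fell. Adjusted over the list alone, 11 rose and 1 fell. Oxidative phosphorylation genes fell as a list (adjusted p = 1.26e-15, and adjusted p = 0.489 with an estimated correlation). In edgeR's fit 0 of 47 had a positive log2 fold change and the median was -0.14. Of these, 1 passed over all genes and 13 were called when adjusted over the list alone. The member that passed was the complex I subunit Ndufs7 at -0.20 (SE 0.04, adjusted p = 0.0353), while Atp5d, of the ATP synthase, was at -0.17 (SE 0.05, adjusted p = 0.0763).

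Protein folding genes fell as lists. The heat shock list was at adjusted p = 0.000976 (adjusted p = 0.326 with an estimated correlation). The steroid receptor cochaperone Fkbp4 was lower at -0.24 (SE 0.06, adjusted p = 0.0490), and Bag3 was at -0.56 (SE 0.15, adjusted p = 0.0807). Over all genes 1 of 16 was lower, against 4 lower and 1 higher adjusted over the list alone. The unfolded protein response list was at adjusted p = 0.00173 (adjusted p = 0.489 with an estimated correlation). Herpud1, of endoplasmic reticulum degradation, was lower at -0.39 (SE 0.09, adjusted p = 0.0446) and was also the 1 of 24 called over the list alone. Glycolysis genes (adjusted p = 0.0172, and adjusted p = 0.752 with an estimated correlation) included the glycolytic regulator Pfkfb3 at -0.38 (SE 0.09, adjusted p = 0.0446), 1 of 18 past the threshold and 4 adjusted over the list alone. NRF2 targets of oxidative stress (adjusted p = 0.00360, and adjusted p = 0.326 with an estimated correlation) and glucocorticoid response genes (adjusted p = 0.0457, and adjusted p = 0.752 with an estimated correlation) had no member past the threshold over all genes, with 0 of 22 and 1 of 20 called adjusted over the list alone. With the share of reads outside genes as a covariate, a choice made after seeing the data, glycolysis (adjusted p = 0.320) and NRF2 genes (adjusted p = 0.134) lost their calls, and the heat shock median was -0.08 in place of -0.12 (adjusted p = 0.0348, and adjusted p = 0.612 with an estimated correlation). Striatal markers, which mark tissue next to the dissected cortex, did not pass (adjusted p = 0.263, 9 of 13 positive, median 0.17, 1 higher adjusted over the list alone and none over all genes). With that covariate they passed as higher, at a median of 0.28 (adjusted p = 0.0348, and adjusted p = 0.846 with an estimated correlation). Glucocorticoid response genes had a median of -0.13, or -0.19 with that covariate (adjusted p = 1.50e-05, and adjusted p = 0.517 with an estimated correlation). They lost their call without ethanol mouse 14 and water mouse 25, whose libraries stood apart (adjusted p = 0.140, median -0.07, also chosen after seeing the data), with the inferred run as a covariate (adjusted p = 0.105) and with the stricter filter (adjusted p = 0.0527).

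Glutamate receptor and synapse genes rose as a list (adjusted p = 0.000592, and adjusted p = 0.489 with an estimated correlation), with 25 of 28 positive. The kainate receptor subunit Grik2 was at 0.35 (SE 0.11, adjusted p = 0.118) and the metabotropic receptor Grm5 at 0.24 (SE 0.08, adjusted p = 0.139). Ribosomal protein genes rose as a list (adjusted p = 0.00363, and adjusted p = 0.862 with an estimated correlation), with 41 of 49 positive and a median of 0.05. This call was lost without ethanol mouse 14 and water mouse 25 (adjusted p = 0.101, median 0.03) and with reads outside genes as a covariate (adjusted p = 0.0941). Homeostatic microglial genes rose as a list (adjusted p = 0.00516, and adjusted p = 0.713 with an estimated correlation), with 17 of 25 positive, and Gpr84, an immune cell receptor for fatty acids, was at 1.43 (SE 0.36, adjusted p = 0.0671). Oligodendrocyte markers fell as a list (adjusted p = 1.12e-05, and adjusted p = 0.752 with an estimated correlation). In edgeR's fit 0 of 20 had a positive log2 fold change, the median was -0.72, and no member passed over all genes or adjusted over the list alone. Their mean log2 CPM was 7.76 and 7.31 in the homogenates of water mice 26 and 17, and 4.99 to 6.35 in the other water homogenates. With ethanol it was 7.04 in mouse 3 and 5.01 to 6.08 in the others. The fall thus leaned on few libraries, and the list was not tested without water mice 17 and 26. Of the glutamate, ribosomal and homeostatic lists no member passed over all genes, and adjusted over the list alone 0, 0 and 3 rose.

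The homogenate immune lists did not pass: interferon (adjusted p = 0.196), Toll-like receptor (adjusted p = 0.631), TGF-beta (adjusted p = 0.658) and NF-kB cytokines (adjusted p = 0.496). Nor did major histocompatibility class I (adjusted p = 0.282) and class II (adjusted p = 0.795) and the disease-associated list (adjusted p = 0.102). Ethanol and acetaldehyde metabolism did not pass either (adjusted p = 0.145), with Aldh1a1 as its member past the threshold. Endothelial markers did not pass (adjusted p = 0.0906) and fell as a list without ethanol mouse 14 and water mouse 25 (adjusted p = 0.0195, and adjusted p = 0.913 with an estimated correlation).

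Within the first inferred run, 4 ethanol against 4 water homogenates, edgeR called 0 genes (1618 with an unadjusted p under 0.05). Within the second, again 4 against 4, it called 0 genes (1314 with an unadjusted p under 0.05). In a comparison chosen after seeing the data, of 1611 genes tested in both runs with an unadjusted p under 0.05 in the first, 81.4% had the same direction in the second. Of 1305 such genes of the second run 77.5% had the same direction in the first, against 60.9% of all 15020 genes, which are not independent replicates. Ethanol homogenates held a larger share of reads outside genes than water homogenates by 4.60 percentage points (exact permutation test, two-sided, p = 0.00425, adjusted p = 0.0128 over 3 comparisons). With this share as a covariate, chosen after seeing the data, edgeR called 0 genes (1190 with an unadjusted p under 0.05).

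The interaction asked whether the ethanol response of microglia differed from that of homogenate. In the fit without pairing 54 of 15797 genes differed, 25 with a more positive response in microglia and 29 with a more negative response. With the mouse as a block, which pairs the preparations of each mouse, edgeR called 0 genes (1132 with an unadjusted p under 0.05), and DESeq2, run without the block, called 270. Fam53b, which fell in homogenate to 45.7 CPM from 70.3 CPM, was at 125 CPM in ethanol and 123 CPM in water microglia, an interaction of 0.63 (SE 0.11, adjusted p = 0.0211). Nuak1 showed an interaction of 0.55 (SE 0.10, adjusted p = 0.0211). That of Tsc22d3, a glucocorticoid-induced leucine zipper gene, was 0.89 (SE 0.19, adjusted p = 0.0291), with 50.6 against 67.3 CPM in ethanol and water homogenate and 475 against 341 CPM in microglia. Rbm33 went the other way at -0.40 (SE 0.08, adjusted p = 0.0211), higher in ethanol homogenate at 119 against 94.1 CPM and at 185 against 192 CPM in microglia. The count of genes moved by over 1.5 times in 19 of 37 fits without 1 library, from 22 without the homogenate of ethanol mouse 5 to 132 without the microglia of ethanol mouse 3. Of 22 named genes past the threshold 12 lost their call in at least 1 of these fits, Tsc22d3 among them (adjusted p = 0.0538 without the microglia of water mouse 19).

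Oligodendrocyte markers were the list that differed between preparations (camera adjusted p = 1.67e-07, and adjusted p = 0.942 with an estimated correlation). All 20 had a positive interaction with a median of 1.37, none passed over all genes in edgeR's fit, and 4 were called when adjusted over the list alone. With the mouse as a block their median was 0.84 (adjusted p = 0.000149). The homogenates of water mice 17 and 26, high in these markers (mean log2 CPM of 7.31 and 7.76), enter the fit without pairing. The block leaves out water mouse 26, which has no microglial library with counts. Lysosomal (adjusted p = 0.0818) and oxidative phosphorylation genes (adjusted p = 0.143) did not pass without pairing, and with the block both passed as more positive in microglia (adjusted p = 0.0340). With the block and an estimated correlation these 3 lists were at adjusted p = 0.921. The immediate early list did not pass (adjusted p = 0.186, 9 of 24 positive). None of its members passed over all genes, and adjusted over the list alone 2 had a more positive and 4 a more negative response in microglia.

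LPS was compared with saline in microglia 1 week after injection. Saa3, an acute-phase serum amyloid A protein made by macrophages, rose to 11.8 ± 6.39 CPM (SD, n = 5) from 0.0301 ± 0.0673 CPM (SD, n = 5), a log2 fold change of 8.14 (SE 1.11, adjusted p = 0.0119). It had between 54 and 634 counts in each LPS library, 6 counts in saline mouse 49 and none in the other saline libraries. Lag3, an inhibitory receptor that binds major histocompatibility class II, rose to 1077 ± 132 CPM (SD, n = 5) from 695 ± 70.9 CPM (SD, n = 5), by 0.63 (SE 0.10, adjusted p = 0.0415). These were the 2 genes called among 12469 by edgeR, with 721 at an unadjusted p under 0.05, while DESeq2 called 73 and voom 30. Saa3 lies on chromosome 7 at 46711998 to 46715700 and Lag3 on chromosome 6 at 124904361 to 124911705.

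Inflammatory genes rose as lists. The NF-kB cytokine list was at camera adjusted p = 8.57e-11 (adjusted p = 0.103 with an estimated correlation). Of its members 25 of 29 were positive, 1 was past the threshold over all genes, Saa3, and 10 were called when adjusted over the list alone. Their median was 0.35, or 0.20 without 4 libraries with many zero counts, of saline mice 38 and 48 and LPS mice 50 and 51, a choice made after seeing the data. The chemokines Ccl5 at 3.02 (SE 0.77, adjusted p = 0.295) and Ccl3 at 0.44 (SE 0.11, adjusted p = 0.270) and the cytokine Il1b at 0.76 (SE 0.20, adjusted p = 0.339) did not pass over all genes. Interferon response genes rose as a list (adjusted p = 3.01e-06, and adjusted p = 0.103 with an estimated correlation), with 27 of 31 positive, none past the threshold over all genes and 2 adjusted over the list alone. With the score of other cell types as a covariate it also passed with an estimated correlation (adjusted p = 0.0331), in a fit added after seeing the data. The chemokine Cxcl10 was at 1.21 (SE 0.25, adjusted p = 0.134) and Lgals3bp at 0.53 (SE 0.11, adjusted p = 0.177). The disease-associated list rose (adjusted p = 0.000426, and adjusted p = 0.103 with an estimated correlation), with Apoe at 0.69 (SE 0.15, adjusted p = 0.159) and the receptor tyrosine kinase Axl at 0.71 (SE 0.24, adjusted p = 0.639). Lysosomal genes rose as a list (adjusted p = 0.000426, and adjusted p = 0.513 with an estimated correlation), with the mannosidase Man2b1 at 0.38 (SE 0.08, adjusted p = 0.183). In each of these 2 lists none passed over all genes and 2 were called when adjusted over the list alone. Without LPS mouse 33 the median of the disease-associated list was 0.10 in place of 0.16 and that of the lysosomal list 0.06 in place of 0.11.

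Heat shock genes fell as a list (adjusted p = 3.03e-22, and adjusted p = 0.103 with an estimated correlation). In edgeR's fit 0 of 16 had a positive log2 fold change, with a median of -0.68, or -0.45 without the 4 libraries with many zero counts (adjusted p = 1.99e-13, and adjusted p = 0.175 with an estimated correlation). Of them 11 were called lower when adjusted over the list alone, against 0 over all genes. The chaperone Hsp90aa1 was at -0.73 (SE 0.14, adjusted p = 0.0882), and its cochaperones Dnaja1 at -0.72 (SE 0.14, adjusted p = 0.0882) and Bag3 at -0.70 (SE 0.13, adjusted p = 0.0882). Hspa1a, whose reads are hard to tell from those of Hspa1b, was at -1.36 (SE 0.28, adjusted p = 0.134). Homeostatic microglial genes fell as a list (adjusted p = 0.00353, and adjusted p = 0.593 with an estimated correlation), with 6 of 25 positive, none called over all genes or adjusted over the list alone, and the protease inhibitor Cst3 at -0.38 (SE 0.12, adjusted p = 0.581). Their median was -0.10, and the call was lost without those 4 libraries (adjusted p = 0.294, median -0.06), without saline mouse 38 (adjusted p = 0.132) or without LPS mouse 40 (adjusted p = 0.0591). Immediate early genes, which tissue dissociation also induces, did not pass as a list (adjusted p = 0.0756, 8 of 23 positive, median -0.05, and adjusted p = 0.474 without those 4 libraries), with 6 lower and 1 higher adjusted over the list alone and none over all genes. They passed as a lower list with the score of other cell types as a covariate (adjusted p = 0.0332) and without LPS mouse 33 (adjusted p = 0.0346, median -0.13), 50 (adjusted p = 0.0366) or 51 (adjusted p = 0.0359, median -0.10) or saline mouse 45 (adjusted p = 0.00326, median -0.12) or 46 (adjusted p = 0.0372, median -0.11). With an estimated correlation these were at adjusted p = 0.554 with the covariate and between 0.486 and 0.671 without 1 library.

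Glycolysis genes rose as a list (adjusted p = 6.83e-05, and adjusted p = 0.103 with an estimated correlation), with 4 of 18 adjusted over the list alone and none over all genes. Pfkfb3 was at 0.51 (SE 0.12, adjusted p = 0.192) and hexokinase Hk2 at 0.39 (SE 0.09, adjusted p = 0.234). The median of the list was 0.25, or 0.15 without LPS mouse 40. Ribosomal protein genes rose as a list (adjusted p = 3.29e-12, and adjusted p = 0.414 with an estimated correlation), with 45 of 49 positive, a median of 0.23 and none called over all genes or adjusted over the list alone. Among blood cell markers, the lymphocyte and monocyte lists passed as higher, and the neutrophil list did not pass. Lymphocyte markers rose as a list at adjusted p = 0.00117 (adjusted p = 0.103 with an estimated correlation), with a median of 0.86, or 1.39 without saline mouse 48. The granzyme Gzma was at 3.59 (SE 0.72, adjusted p = 0.134) and the natural killer receptor Ncr1 at 5.87 (SE 1.51, adjusted p = 0.318), both called when adjusted over the list alone, against none over all genes. Monocyte markers were at adjusted p = 0.0466 (adjusted p = 0.513 with an estimated correlation), with none called. They lost the call without LPS mouse 40 (adjusted p = 0.187, median 0.22 in place of 0.48), 44 (adjusted p = 0.0750) or 51 (adjusted p = 0.0780) or saline mouse 45 (adjusted p = 0.0579) or 49 (adjusted p = 0.262, median 0.29), with RLE scaling (adjusted p = 0.0523) and with the stricter filter (adjusted p = 0.0537). Neutrophil markers did not pass (adjusted p = 0.0756, 10 of 12 positive, median 0.35). Without the 4 libraries with many zero counts they had the smallest p of the lists tested, with a median of 1.31 (adjusted p = 6.36e-33, and adjusted p = 0.137 with an estimated correlation), and monocyte markers were at a median of 0.70 (adjusted p = 3.85e-05, and adjusted p = 0.310 with an estimated correlation). Neutrophil markers also passed without LPS mouse 50 (adjusted p = 0.00102) or 51 (adjusted p = 0.00672), without saline mouse 38 (adjusted p = 0.0159) or 48 (adjusted p = 0.000311, median 0.63) and with the stricter filter (adjusted p = 0.0475). In these fits they were between adjusted p = 0.480 and 0.685 with an estimated correlation.

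Markers of other brain cells did not pass after LPS. Endothelial, mural and fibroblast, oligodendrocyte, astrocyte and oligodendrocyte precursor markers passed without single libraries, and neuronal markers did not. Endothelial markers (adjusted p = 0.0640, median -0.21) were lower without LPS mouse 40 (adjusted p = 0.000246, median -0.47) or 44 (adjusted p = 0.0443) or saline mouse 38 (adjusted p = 0.0388), 48 (adjusted p = 0.00447) or 49 (adjusted p = 0.0313). Mural and fibroblast markers (adjusted p = 0.118, median -0.56) were lower without LPS mouse 33 (adjusted p = 0.0346) or 40 (adjusted p = 0.0212) or saline mouse 38 (adjusted p = 0.0217) or 48 (adjusted p = 0.0416). Oligodendrocyte markers (adjusted p = 0.0972, median -0.35) were lower without LPS mouse 40 (adjusted p = 0.0434) or 50 (adjusted p = 0.00379, median -0.55) or saline mouse 48 (adjusted p = 0.0430) or 49 (adjusted p = 0.0448). Without LPS mouse 33 or saline mouse 46, astrocyte markers (adjusted p = 0.185, median 0.35) were higher at adjusted p = 0.0346 and 0.0361. In the same fits oligodendrocyte precursor markers (adjusted p = 0.169, median 0.74) were higher at adjusted p = 0.0220 and 0.0414, with medians of 1.15 and 1.39. In those fits these 5 lists were between adjusted p = 0.404 and 0.780 with an estimated correlation, and in the full comparison no member of them was called over all genes or adjusted over the list alone.

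Tlr4 was at 0.20 (SE 0.21, adjusted p = 0.987), Cd14 at 0.09 (SE 0.11), and Tnf at 0.35 (SE 0.13, adjusted p = 0.717). Tgfb1 was at -0.06 (SE 0.10), Tgfbr1 at 0.01 (SE 0.11), P2ry12 at -0.20 (SE 0.08), Cx3cr1 at -0.14 (SE 0.07) and Tmem119 at -0.17 (SE 0.11). The Toll-like receptor (adjusted p = 0.264), TGF-beta (adjusted p = 0.216) and major histocompatibility class I (adjusted p = 0.0756) and class II (adjusted p = 0.372) lists did not pass. Without the 4 libraries with many zero counts class I (adjusted p = 0.000268, and adjusted p = 0.310 with an estimated correlation) and complement genes (adjusted p = 0.000995, against 0.139, and adjusted p = 0.235 with an estimated correlation) passed. Class I also passed as higher without LPS mouse 40 (adjusted p = 0.0466) or saline mouse 38 (adjusted p = 0.00415) or 48 (adjusted p = 0.0416), and complement without LPS mouse 51 (adjusted p = 0.0449). TGF-beta genes passed as lower without saline mouse 38 (adjusted p = 0.0291, median -0.13 in place of -0.10), and oxidative phosphorylation genes (adjusted p = 0.211, median -0.10) without saline mouse 48 (adjusted p = 0.0446, median -0.18). These 4 lists were between adjusted p = 0.270 and 0.536 with an estimated correlation in the fits without 1 library.

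**Figure D3:**
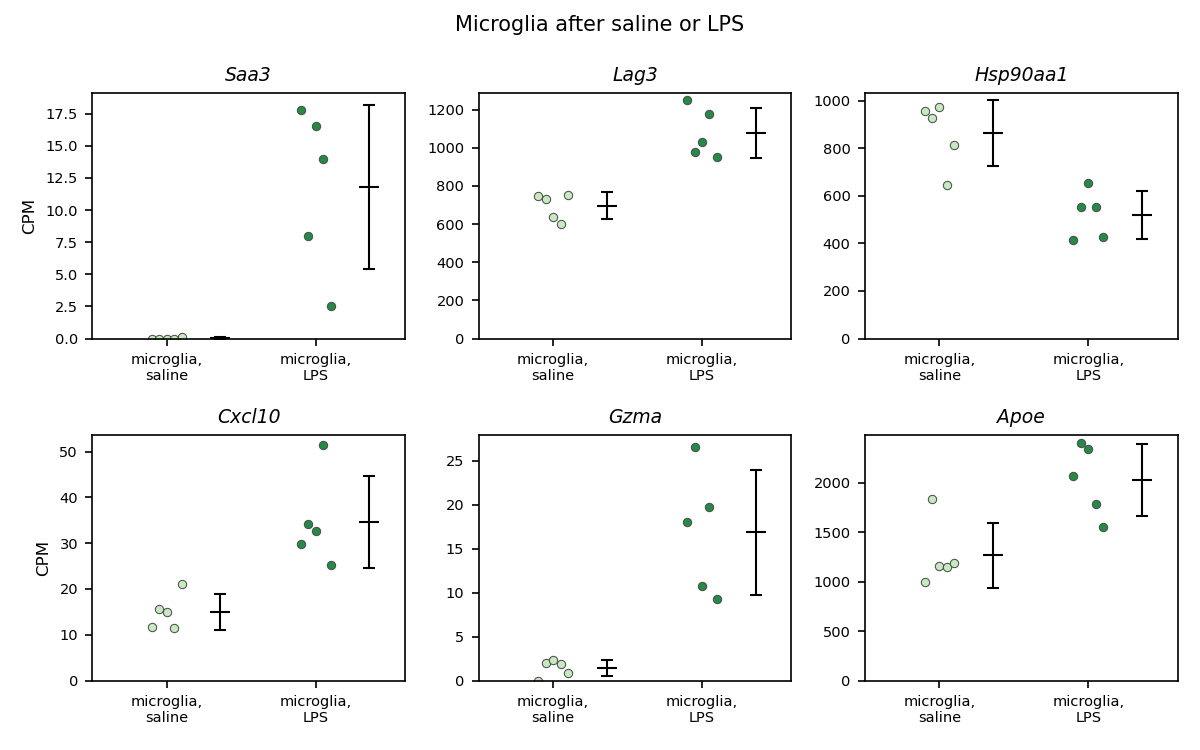
CPM per library of 6 genes in microglia of 5 saline and 5 LPS mice, as points, with the mean and SD as a bar and whiskers. Saa3 and Lag3 passed the threshold, and Hsp90aa1, Cxcl10, Gzma and Apoe did not, at adjusted p of 0.0882, 0.134, 0.134 and 0.159.

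Saa3 lost its call without LPS mouse 33 (adjusted p = 0.0802), 44 (adjusted p = 0.0559) or 50 (adjusted p = 0.0763) or saline mouse 46 (adjusted p = 0.0540). Over its 6 alternatives other than left-out libraries the adjusted p of Saa3 ran from 0.000312 to 0.0356, and DESeq2 gave it none. Lag3 lost its call without LPS mouse 33 (adjusted p = 0.0836), 40 (adjusted p = 0.104), 44 (adjusted p = 0.0559) or 50 (adjusted p = 0.259) or saline mouse 46 (adjusted p = 0.269), 48 (adjusted p = 0.0955) or 49 (adjusted p = 0.129). It also lost it with the score of other cell types as a covariate (adjusted p = 0.0676), where its log2 fold change was 0.64 (SE 0.11) beside 0.63 (SE 0.10). Without the 4 libraries with many zero counts, a choice made after seeing the data, it was at 0.63 (SE 0.11, adjusted p = 0.0678), in a range of adjusted p from 5.72e-08 to 0.0678 over its 7 alternatives.

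The microglial ethanol and LPS comparisons used separate control mice and shared no called gene in edgeR's test. Among 12354 genes tested in both, 1 was called with ethanol and 1 with LPS, and DESeq2 also shared 0 genes, of 36 and 73 called. At an unadjusted p under 0.01, 135 genes were higher with ethanol and 110 with LPS, sharing Lrrc3, where independent lists would share 1.20 (Fisher's exact test, two-sided, p = 1). At the same threshold 152 and 73 were lower, sharing 0 where 0.898 would be shared (Fisher's exact test, two-sided, p = 1). Genes going opposite ways, compared and named after their values were seen, were more than independent lists would share. Fisher's test counts genes as independent, which genes that move together in a library are not. Its p therefore does not measure the spread between mice, and an opposed response is not settled by it. Aars, Fosb, Klf2 and Klf4 were higher with ethanol and lower with LPS, 4 where 0.798 would be shared (Fisher's exact test, two-sided, p = 0.00830, adjusted p = 0.0332). Alpk1, Ankzf1, Ascc3, C3, Ccl3 and Plin2 were lower with ethanol and higher with LPS, 6 where 1.35 would be shared (Fisher's exact test, two-sided, p = 0.00235, adjusted p = 0.0188). Across genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of -0.104 and a Spearman correlation of -0.0840, and 47.0% had the same sign.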

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

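The tests of the share of reads outside genes and of the run for homogenate genes, the test of lymphocyte markers without libraries with many zero counts and the counts of splits for single lists were chosen after the result was seen.

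The first pattern was the 123 genes called between ethanol and water homogenates, beside a share of reads outside genes that was 4.60 percentage points higher in ethanol homogenates. Over 14514 genes with a known length, the log2 fold change had a Spearman correlation of 0.0847 with length and -0.0412 with GC content. Once a trend with both was taken off, 115 of the called genes kept a median of 97.5% of their fold. So flat a trend could take little from genes picked for their fold. The values argue against a smooth trend over all genes as the whole cause, and give no answer on an effect limited to few genes. A term for the inferred run (101% kept) gives no answer, as the runs held ethanol and water homogenates in like numbers (4 and 4, 4 and 4, 2 and 1). With the share of outside reads as a covariate the 123 called genes kept a median of 79.6%, the median size going from 0.34 (median SE 0.07) to 0.27 (median SE 0.08), 122 of them at an unadjusted p under 0.05 and 0 called by edgeR, as the fold shrank and its error grew. This share differs with the drinking group, so its part and that of ethanol cannot be told apart, and both may contribute. Chance could be excluded for the gene count: 1 of 100 splits, the real one, gave 123 genes, and the highest other gave 30.

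The second pattern was the rise of immediate early genes after ethanol in both preparations. The median fold was above 0 in 4 of 4 fits within an inferred run and preparation, which gives no answer on the run either, as the runs held ethanol and water libraries in like numbers. With the marker score of neurons, astrocytes, oligodendrocytes and endothelial cells as a covariate, the median fold in microglia kept 100.4%. Mean log2 CPM of these markers in ethanol against water microglia was 1.98 against 1.68, 2.60 against 2.63, 3.62 against 3.22 and 3.76 against 4.11. Their SD ran from 0.53 to 1.13 (n = 10 and 8). A covariate so alike in both groups can take little of a fold away, so the kept share gives no answer on RNA of these cells. The score holds no neutrophil, monocyte or border macrophage markers, so it gives no answer on those cells either. Without water mice 19 and 24 the median log2 fold change was 0.16 in place of 0.22. In saline microglia of the separate cohort the mean log2 CPM of the list was 9.36, beside 9.32 with ethanol and 9.10 with water. For this list 1 of 100 splits of the microglia and 2 of 100 of the homogenates, the real ones included, gave a p as small, but in 13 and 47 of them some list reached such a p, so chance could not be excluded for a list picked among 36. A response to ethanol, or to the time and handling of the tissue, may underlie it, and the design does not separate these.

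The third pattern was the rise of lymphocyte markers in microglia after LPS. Against low complexity of some libraries, the median fold of the list went to 145% of its value when the 4 libraries with many zero counts were left out. In that fit neutrophil and monocyte markers also rose, with medians of 1.31 and 0.70. Of the 10 measured markers 70% were positive: Gzma stood at 16.9 ± 7.07 CPM (SD, n = 5) with LPS and 1.42 ± 0.956 CPM (SD, n = 5) with saline, and Il7r at 25.8 and 17.4 CPM, while Cd79b stood at 8.20 and 11.001 CPM. Natural killer cells, which carry CD11b and so can pass the beads, could be a source of Gzma and Ncr1, and whether lymphocytes were among the isolated cells cannot be told apart from expression in microglia with markers that went both ways.

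For the other gene counts, only the real split of 100 called genes between preparations (12712 genes, highest other 0). Splits that mix such different libraries put their difference into the spread, so this outcome was nearly certain beforehand and adds little. In microglia after ethanol 3 of 100 splits gave as many (1 gene, highest other 1), and after LPS 2 of 100 (2 genes, highest other 2). Such splits were rare, but not only the real ones matched these counts, and both counts went to 0 without single libraries. Chance was therefore not firmly excluded for them. Nor could it be excluded for the interaction (54 genes, 6 of 100 splits, highest other 97). It could not be excluded for these counts of lists: 5 lists in microglia after ethanol (98 of 100 splits, highest other 18), 11 in homogenate (55 of 100, highest other 26), 1 for the interaction (100 of 100, highest other 21) and 10 after LPS (18 of 100, highest other 16). Between preparations 45 of 100 splits gave as many as the 24 lists (highest other 32). Splits that mix such different libraries unevenly may carry part of their difference, which was not tested, so this count gives no answer.

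For single lists, splits in which some list of the comparison reached a p as small as the real one, the real split included, were counted too, and chance could not be excluded for any called list after ethanol, in the interaction or after LPS. Their lowest numbers of 100 were 13 for immediate early genes in microglia after ethanol, 16 for oxidative phosphorylation in homogenate, 49 for oligodendrocyte markers in the interaction and 7 for heat shock genes after LPS. Counted for the list itself, without adjustment over the lists, splits with a p as small numbered 21 for glycolysis, 23 for border macrophage, 24 for oligodendrocyte and 39 for homeostatic genes in microglia after ethanol. In homogenate they numbered 2 for heat shock and 2 for NRF2 genes, 5 for oxidative phosphorylation, 9 for glutamate receptor and synapse, 11 for homeostatic, 12 for unfolded protein response, 20 for glycolysis, 24 for glucocorticoid response, 31 for oligodendrocyte and 47 for ribosomal protein genes. After LPS they numbered 1 for interferon and 1 for lymphocyte genes, 2 for glycolysis, 2 for disease-associated, 3 for heat shock, 4 for NF-kB cytokine, 8 for lysosomal, 9 for ribosomal protein, 19 for homeostatic and 26 for monocyte genes, and in the interaction 11 for oligodendrocyte markers.

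Libraries far from the rest of their group were looked for in each measure, and chance alone marks about 1 in 20 groups. The microglia of water mouse 24 held 56.1% of reads outside genes (nearest 27.1%), 10.3% of counts in the ribosomal RNA gene Rn45s (nearest 0.677%) and 8.45% in Lars2 (nearest 0.638%). The homogenate of ethanol mouse 14 held 6.23% in Rn45s (nearest 0.786%) and 0.700% in Lars2 (nearest 0.138%), and that of water mouse 15 0.642% in Rn45s (nearest 0.357%) and 0.929% zero counts among genes of low expression (nearest 0.383%). Microglia of ethanol mouse 5 held 21.03% such zero counts (nearest 10.2%), the homogenate of water mouse 17 26.8% of reads outside genes (nearest 23.5%), and that of ethanol mouse 13 17867 detected genes (nearest 17155).

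Mean log2 CPM of marker lists set further libraries apart. In water mouse 19 neutrophil markers were at 9.92 in microglia (nearest 4.42) and 0.39 in homogenate (nearest -1.74), and monocyte markers at 6.81 in microglia (nearest 2.72). Monocyte markers were at 1.35 in LPS mouse 50 (nearest 2.81), choroid and ependymal markers at -2.71 in LPS mouse 44 (nearest -3.52) and 2.16 in the homogenate of water mouse 25 (nearest 0.43). Border macrophage markers were at 3.20 in saline mouse 38 (nearest 4.73), neuronal markers at 0.79 in saline mouse 48 (nearest 1.60), oligodendrocyte markers at 7.04 in the homogenate of ethanol mouse 3 (nearest 6.08) and striatal markers at 5.86 in that of ethanol mouse 7 (nearest 4.84).

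These genes passed as differing in ethanol response between microglia and homogenate in the fit without pairing, given as log2 interactions. With the mouse as a block edgeR called none, and 6 of 100 splits of the mice, the real one included, gave as many genes as the fit without pairing. Those more positive in microglia were Snx24 at 1.04, Nudt16 at 1.00, Mrm1 at 0.93, Abcb9 at 0.90, Tsc22d3 at 0.89, Tspan9 at 0.73, Fam53b at 0.63, Nuak1 at 0.55, Tm6sf2 at 6.63, Moxd1 at 5.74 and Smad9 at 4.49. Those more negative were Rbm33 at -0.40, Prss57 at -9.78, Tert at -7.45, Tnfrsf8 at -6.19, Fam229b at -5.55, Maats1 at -5.46, Gpr63 at -5.40, Figf at -5.09, Lpin3 at -4.97, Entpd3 at -4.92 and Acta1 at -4.35. In 8 of the 22 a group had no counts, so their fitted values are no bound, and Prss57 was at adjusted p = 1.00 without the microglia of water mouse 19. Figf, Acta1 and Entpd3 were at 0.0031, 0.0031 and 0.0032 CPM in ethanol microglia. Moxd1 and Smad9 were at 0.0048 and 0.021 CPM in water microglia, so the values of these genes rest on hardly any counts there. Oligodendrocyte markers were the list that differed (adjusted p = 1.67e-07, and adjusted p = 0.942 with an estimated correlation).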

How the results depend on the processing

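The covariate of reads outside genes and the fits without libraries that stand apart or have many zero counts were chosen after the result was seen, as were the estimated correlations in fits other than the full ones. Of the alternative values of named genes 2914 kept their direction and side of the threshold, 70 passed newly, 149 no longer passed and 30 changed sign, none of these past the threshold either way. Where no cause is named below, the cause was not tested.

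Against 1 gene in microglia after ethanol, DESeq2 called 50, voom 10, the first run 0 (578 at an unadjusted p under 0.05), the second run 4 and the cell type covariate 4. Against 123 in homogenate, DESeq2 called 526, voom 568, no filter 62 (more genes tested), the first and second run 0 and 0 (fewer samples, 1618 and 1314 at an unadjusted p under 0.05) and the covariate of outside reads 0 (1190). Against 54 for the interaction, DESeq2 called 270, the stricter filter 35, the run as covariate 35 and the mouse as a block 0 (1132 at an unadjusted p under 0.05). Against 2 after LPS, DESeq2 called 73, voom 30, no filter 17, the cell type covariate 1 and the fit without 4 libraries with many zero counts 5. With an estimated correlation the lists called were 1 of 5 in microglia after ethanol, 0 of 11 in homogenate, 0 of 1 for the interaction, 0 of 10 after LPS and 5 of 24 between preparations. Without the libraries that stand apart 9 lists passed in microglia after ethanol, and of the called lists immediate early, border macrophage and oligodendrocyte genes kept their call. With an estimated correlation as well, 0 lists passed in microglia after ethanol (3 at an unadjusted p under 0.05), 0 in homogenate (4) and 0 after LPS (6). Over all settings with lists and an estimated correlation, 0 to 1 lists passed in 5 settings in microglia after ethanol, 0 in 5 in homogenate, 0 in 4 for the interaction, 0 to 1 in 14 after LPS and 1 to 4 in 3 between preparations. The block gave 3 lists for the interaction and 12351 genes and 30 lists between preparations, where oligodendrocyte, monocyte, mural, cell cycle, circadian clock and heat shock genes passed newly, and changed no other list call. With the block and an estimated correlation, these newly passing lists between preparations were at adjusted p from 0.235 to 0.513. At an unadjusted p under 0.01 the ethanol and LPS comparisons shared 1 gene.

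Leaving out each library in turn gave 0 to 7 genes in microglia after ethanol: 4, 2 and 5 without ethanol mice 2, 13 and 14, and 3, 0, 0, 7, 0 and 7 without water mice 15, 16, 18, 19, 21 and 25. In homogenate it gave 39 to 275: 275, 50, 231, 55, 71, 58, 54 and 70 without ethanol mice 1, 2, 3, 5, 7, 9, 10 and 13, and 57, 39, 57, 185 and 55 without water mice 17, 18, 19, 24 and 26. For the interaction it gave 22 to 132: 32, 22, 29, 29, 27, 34, 30 and 30 without homogenates of ethanol mice 2, 5, 7, 9, 10, 11, 13 and 14, 32, 29, 32, 27 and 26 without those of water mice 15, 17, 18, 19 and 26, 132 and 35 without microglia of ethanol mice 3 and 5, and 115, 108, 110 and 93 without those of water mice 17, 18, 21 and 25. After LPS it gave 0 to 6: 0, 1, 0 and 0 without LPS mice 33, 40, 44 and 50, and 5, 6, 0, 1 and 1 without saline mice 38, 45, 46, 48 and 49, with 10 to 16 lists, 16 without saline mouse 48. Between preparations it gave 12420 to 12868. Of named genes past the threshold 12 of 24 in homogenate, 12 of 22 for the interaction and 0 of 125 between preparations lost their call at least once.

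The log2 values that changed sign in microglia after ethanol were, in DESeq2, Lgals3 at 0.79 and Lyz2 at 0.17, in voom Lgals3 at 1.10 and Lyz2 at 0.019, and without the libraries that stand apart Lgals3 at 0.91 and Lyz2 at 0.15. Within the first run they were Apoe at 0.028, H2-DMb2 at -0.057, Il1b at -0.15 and Tgfbr1 at 0.061, and within the second Gpi1 at 0.10, H2-K1 at -0.0028, Ifitm3 at 0.10, Il1b at -0.042, Irak3 at 0.10, Lyz2 at 0.063, P2ry12 at -0.053, Sp100 at 0.034, Tgfb1 at -0.0060 and Tgif2 at -0.037. In homogenate they were H2-Ab1 at 0.063 in DESeq2, Slfn2 at 0.047 and Tnfaip3 at 0.12 with the covariate of outside reads, and Bmpr2 at -0.0040 and Mx2 at -0.065 within the second run. For the interaction H2-Aa was at -0.12 in voom. After LPS they were Nr4a1 at -0.062, Tgfbr1 at -0.085 and Tlr4 at -0.026 without the libraries with many zero counts, and Tgfbr1 at -0.083 in voom.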

Other observations

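The comparison of saline with water microglia and the genes shared between preparations were chosen after the data were seen.

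Further immune genes were higher in isolated microglia than in homogenate of water mice. All 18 measured genes of major histocompatibility class I, which presents peptides to cytotoxic lymphocytes, rose with a median log2 fold change of 3.05 (camera adjusted p = 7.50e-07, and adjusted p = 0.201 with an estimated correlation), and 13 of 14 of class II rose with a median of 4.49 (adjusted p = 0.000259, and adjusted p = 0.201 with an estimated correlation). Complement genes rose in 10 of 19 and fell in 4 (adjusted p = 1.32e-06, and adjusted p = 0.0784 with an estimated correlation), and disease-associated genes rose in 17 of 26 and fell in 6 (adjusted p = 7.52e-05, and adjusted p = 0.201 with an estimated correlation). TGF-beta pathway genes rose in 22 of 34 and fell in 11 (adjusted p = 0.00175, and adjusted p = 0.362 with an estimated correlation), and ribosomal protein genes rose in 41 of 49 and fell in 3 (adjusted p = 0.00509, and adjusted p = 0.699 with an estimated correlation). Adjusted over the list alone, these numbers were the same. Interferon response genes rose in 28 of 32 and fell in 1, or 2 adjusted over the list alone (adjusted p = 0.00137, and adjusted p = 0.386 with an estimated correlation).

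At an unadjusted p under 0.01, ethanol microglia and homogenate shared 10 higher genes, Adamts16, Btg2, Dhx34, Fosb, Gas5, Ier2, Jun, Srsf5, Srsf7 and Zc3h6, where independent lists would share 5.69 (Fisher's exact test, two-sided, p = 0.0796, adjusted p = 0.385). They shared 7 lower genes, Apbb2, Banp, Cstb, Fkbp4, Ndufs7, Stip1 and Tmc7, where 3.62 would be shared (Fisher's exact test, two-sided, p = 0.0962, adjusted p = 0.385), so neither overlap passed.

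Adamts16 stood at 36.0 ± 3.54 CPM (SD, n = 5) in saline microglia and 25.1 ± 8.72 CPM (SD, n = 5) in LPS microglia, beside 37.1 CPM with ethanol and 18.2 CPM with water. Saline exceeded water by 17.7 CPM (exact permutation test, two-sided, p = 0.000777, the smallest that 1287 splits can give, adjusted p = 0.00466 over 6 items). The mean log2 CPM of immediate early genes was 9.36 in saline, 9.32 in ethanol and 9.10 in water microglia, and saline exceeded water by 0.25 (exact permutation test, two-sided, p = 0.0163, adjusted p = 0.0490). The other items, Btg2, Egr1, Ier2 and Fosb, did not pass in the same test (adjusted p = 0.448, 0.364, 0.109 and 0.870). Saline and water mice belong to separate cohorts and all saline libraries to the third inferred run, where the ethanol microglia of mice 1 and 13 were at 47.9 and 38.05 CPM of Adamts16 and those of water mouse 15 at 23.3 CPM.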
